A study of Arabidopsis thaliana with 12 samples.

How the data were processed

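The study measured messenger RNA in roots of Arabidopsis thaliana seedlings 6 days after exposure to light, in wild type (accession Col-0) and in the myb36-1 mutant. MYB36 is a transcription factor of the endodermis, the cell layer that surrounds the vascular tissue and deposits the Casparian strip. Per the labels' protocols, whole roots were either frozen at harvest or digested to protoplasts, sorted by fluorescence for the endodermal population and then frozen. The kit for RNA extraction differed between whole roots and sorted cells, and all libraries were made with a strand-specific kit. Per the labels there were 4 groups of 3 biological replicates, 12 libraries in all, and each library was placed in its group by its own description.

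The authors deposited a table of raw read counts per gene for all 12 libraries, without normalization. The authors also deposited normalized counts, here treated as a signal, for each tissue separately. Dividing the raw counts by these values gave 1 constant per library, which equalled the DESeq2 size factor of that tissue's 6 libraries. The authors' deposited tables of gene expression tests hold 1 FPKM per genotype with replicates pooled, its log2 ratio of mutant over wild type, and a p-value and q-value, per the file headers. In the log2 column of those deposited tables, the value is 0 where both FPKM are 0 or the status is FAIL or HIDATA, and other ratios with 0 on 1 side are coded as infinite. TopHat2, SAMtools, Cufflinks, Cuffdiff and HTSeq are named with the genome build TAIR10 in the submitters' processing notes. The version and role of each tool, and whether counting used the strand of the reads, are not given in the sources used here. The count table held 33602 loci, of which 32835 were found in the TAIR10.1 reference annotation used for gene names, coordinates and overlaps. A symbol is given where a gene has one, otherwise the locus identifier.

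Total counts ranged from 17721913 to 24274637 in the wild-type sorted libraries, from 7280556 to 13427477 in the mutant sorted libraries, and from 19812171 to 22722091 in whole roots. A gene with 0 counts in a library allowed at most 3 counts, which is 0.124 to 0.412 CPM depending on the library. Where all 3 libraries of a group were at 0, a fold is given as a lower bound against 3 counts summed over that group. Where a group held 1 to 3 counts in all, the ratio is given with an exact 95% interval. These intervals and floors cover counting error only. Replicates were compared before averaging, and no pair differed by as little as sampling noise. Groups of 3 were too small for a test of single outlying libraries.

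Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM factors, filterByExpr by group) with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. An adjusted p given for a gene comes from this test unless an alternative is named beside it. The comparisons were mutant against wild type in sorted endodermis, the same in whole roots, the difference between these 2 effects (an interaction term over all 12 libraries), and wild-type sorted endodermis against wild-type whole root. In the last of these, cell type, protoplasting, sorting and RNA kit cannot be separated. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries, with the scale set by the libraries of each comparison. A standard error (SE) given for a log2 fold change is its absolute size divided by the square root of the edgeR F statistic. It is derived from the test and is not a separately fitted error.

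A total of 18 gene lists with 240 members were written from textbook knowledge: Casparian strip, suberin, phenylpropanoid and monolignol synthesis, DNA replication and S phase, mitosis and cytokinesis, root meristem regulators, ground tissue identity, xylem, phloem, stele and pericycle, root hair and epidermis, cortex, root cap, wounding and rapid stress response, iron deficiency, aquaporins, abscisic acid response, and nitrate and phosphate transport. Each list was tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation and fry served as alternatives. Overlap of calls was tested with Fisher's exact test, which takes genes as independent. A second root hair list was written before its own test, and lists of ER body genes and of defence-type lignin genes were written after the data had been seen.

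The genes to be named were fixed by rule. MYB36 was named in every library. Among called genes with at least 5 CPM in a group and no overlap between the groups' libraries, the 6 largest rises and 6 largest falls by fitted fold change were named in endodermis, 5 and 5 in whole roots, and 3 and 3 for sorting. For the interaction, 3 and 3 were named without the overlap condition. Where a group is at 0 counts the fitted change depends on the prior count, so this order is no ranking of measured folds. From each list the called members with the smallest p were named: in endodermis 2 (6 for the Casparian strip, 3 for S phase and for mitosis), and in whole roots and sorting 1 (6 and 3 for the Casparian strip). A gene named for one genotype comparison may be quoted in the other. The groups, tests, lists, naming rule and all alternatives other than thinning were fixed before the data were examined.

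The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, a mean of at least 20 counts, limma-voom with quality weights, the replicate number as a block, removal of organelle, rRNA and tRNA genes, 1 fit of all 12 libraries, and leaving out each library in turn. Thinning the sorted libraries to 1 depth was added after seeing the data. The tests were first tested on simulated counts, in which 200 genes were changed. Each gene kept its mean over the libraries of a comparison and 1 fitted spread shared by those libraries, at the real library sizes. In the endodermis simulation of 18318 genes, 3% of 2-fold and 68% of 4-fold changes were recovered, and 4.05% of the calls were false. In the whole-root simulation of 19624 genes, 94% of 2-fold and 100% of 4-fold changes were recovered, and 7.18% of the calls were false. For the interaction over 20302 genes, 5% of 2-fold and 63% of 4-fold changes were recovered, and for sorting over 19747 genes 79% and 100%. False calls made up 4.23% of the interaction calls and 3.76% of the sorting calls. The common biological coefficient of variation behind this was 0.395 in endodermis and 0.148 in whole roots. With 200 changed genes the simulations gave fewer calls than the real data, so their adjusted threshold was stricter. The recovered shares are therefore not those of the real tests. The shared spread also leaves out that mutant sorted replicates varied more than wild-type ones (rank correlations 0.906 to 0.929 against 0.978 to 0.987). The simulated false-call shares therefore do not cover an unequal spread between groups.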

Results

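RNA was sequenced from 6-day-old Arabidopsis roots in 4 groups of 3 biological replicates: wild-type sorted endodermis, myb36-1 sorted endodermis, wild-type whole root and myb36-1 whole root. The 3 wild-type sorted libraries held 19652079, 24274637 and 17721913 counts, and the 3 mutant sorted libraries 13427477, 7874107 and 7280556. The whole-root libraries held 22722091, 21549388 and 20928259 counts in wild type and 19812171, 19816062 and 21691381 in the mutant. Rank correlations between replicates were 0.906 to 0.929 in the mutant sorted group, the lowest of the 4 groups, and 0.978 to 0.994 elsewhere. Mitochondrial genes took 2.84% to 4.29% of counts in the wild-type sorted libraries, 3.75% to 7.46% in the mutant sorted libraries and 1.15% to 1.5% in whole roots. The study's title puts MYB36 at the transition from proliferation to differentiation, and the comparisons below ask which transcripts depended on the myb36-1 genotype in the endodermis and in the root.

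MYB36 transcript (AT5G57620, TAIR10.1 chromosome 5, 23334767 to 23336632, 3 exons) was still counted in every mutant library. In whole roots it was lower in the mutant, at 19.5 ± 1.48 CPM against 34.9 ± 2.42 (log2 fold change -0.84, SE 0.11, edgeR adjusted p = 0.00252). In sorted endodermis it was 122 ± 50 CPM in the mutant and 179 ± 61.2 in wild type, a difference within the spread (log2 -0.55, SE 0.35, edgeR adjusted p = 0.273). The raw counts were 2487, 4057 and 4417 in wild-type sorted cells, 1100, 1522 and 695 in mutant sorted cells, 747, 798 and 739 in wild-type whole roots, and 419, 387 and 377 in mutant whole roots. The labels do not say where the myb36-1 lesion lies, so these counts do not check the genotype of a library. The whole-root call was lost in 1 fit of all 12 libraries (edgeR adjusted p = 0.358, range over the 15 alternatives 2.27e-07 to 0.358).

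In sorted mutant endodermis, Casparian strip genes fell, while genes of suberin and phenylpropanoid synthesis rose. The peroxidase gene PER9 dropped from 540 ± 98.1 to 1.79 ± 0.522 CPM, and the dirigent gene DIR16 from 843 ± 189 to 4.67 ± 2.81. The suberin oxygenase gene CYP86B1 rose from 1.21 ± 0.574 to 49.7 ± 11.7 CPM, and PAL1, which encodes the entry enzyme of the phenylpropanoid pathway, from 131 ± 53.0 to 1829 ± 141. Of 18318 genes tested, 2857 were higher and 2368 lower in the mutant (edgeR adjusted p under 0.05). Leaving out wild-type replicate 1, 2 or 3 reduced these 5225 calls to 2512, 2236 or 2764. Leaving out mutant replicate 1, 2 or 3 raised them to 7017, 5900 or 5444, and 1 fit of all 12 libraries raised them to 9251. With the sorted libraries thinned to 7280556 counts each, an alternative chosen after seeing the data, 5002 genes were called, including 4821 of the 5225.

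Of 21 Casparian strip genes, 13 fell, 4 rose and 4 were not called in mutant endodermis, with a median log2 fold change of -1.93 (13 lower and 5 higher adjusted over the list alone). The list stood lower than other genes (camera adjusted p = 9.25e-11), a call lost at adjusted p = 0.190 with an estimated correlation, the highest of the 9 alternatives (lowest 2.68e-16). PER9 (AT1G44970, chromosome 1, 17002089 to 17003867, 4 exons) had a log2 fold change of -8.20 (SE 0.35, edgeR adjusted p = 6.12e-05) and DIR16 (AT3G24020, chromosome 3, 8678678 to 8679656, 1 exon) of -7.53 (SE 0.60, edgeR adjusted p = 3.32e-04). The dirigent genes DIR9, DIR18 and DIR24 fell by 6.38, 5.76 and 3.85 on the log2 scale. CASP1, which encodes a membrane scaffold protein of the strip, fell from 928 ± 320 to 80.8 ± 28.9 CPM and CASP2 had a log2 fold change of -6.73, while PER64 and ESB1 fell by 2.18 and 1.21. The 4 members that rose, named after their values were seen, were GSO1, which encodes a receptor kinase of the barrier surveillance pathway (log2 2.44), RBOHF, an NADPH oxidase gene (1.56), and the peroxidase genes PER3 (2.57) and PER39 (1.60). DIR9, DIR18, CASP1, PER64 and ESB1 overlap antisense genes, as do KCS2, KNOLLE, CDKB2;2, GL2, AED3, F6H1, SKOR, WRKY53, NRT1.5, ABCG2, MCM7, CYCA2;3 and WRKY40, given below, and reads of such pairs cannot be told apart unless counting used strand.

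**Figure D1:**
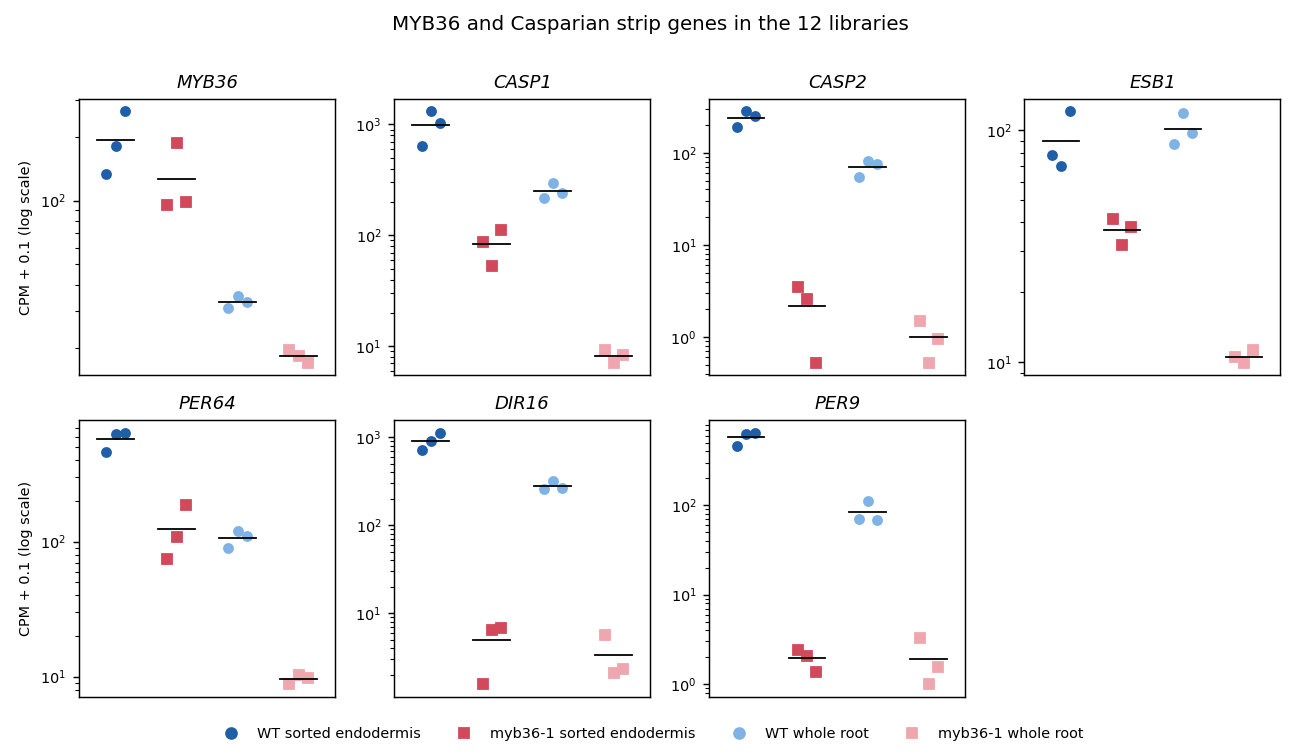
Levels of MYB36 and 6 Casparian strip genes in each of the 12 libraries, as TMM-scaled CPM plus 0.1 on a log axis, with 1 point per library and a line at each group's mean. For CASP1, CASP2, PER64, DIR16 and PER9 every mutant library lies below every wild-type library of its tissue, whereas the sorted mutant and wild-type points of MYB36 overlap.

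Suberin genes moved the other way in mutant endodermis: 17 of 21 rose, 0 fell and 4 were not called, with a median log2 fold change of 2.89 (19 higher adjusted over the list alone). The camera adjusted p was 1.41e-13, and the call was lost at adjusted p = 0.0687 with an estimated correlation, the highest of 9 alternatives (lowest 1.24e-15). CYP86B1 (AT5G23190, chromosome 5, 7803141 to 7805968, 2 exons) rose by 5.35 on the log2 scale (SE 0.45, edgeR adjusted p = 3.70e-04), and KCS2, which encodes a fatty acid elongase, rose from 6.18 ± 0.950 to 48.4 ± 8.20 CPM (log2 2.97). Of 18 phenylpropanoid and monolignol genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.48 (camera adjusted p = 2.98e-10; adjusted p = 0.190 with an estimated correlation, lowest of the 9 alternatives 1.04e-11). PAL1 rose by 3.80 on the log2 scale (SE 0.33, edgeR adjusted p = 3.93e-04) and CAD4, of the last step of monolignol synthesis, by 3.02. Beside these rises, markers of other root cells moved between the sorted libraries. Root cap and root hair genes were lower in the mutant, and wounding genes higher, as given next.

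Root cap and epidermal markers were lower in the sorted mutant libraries than in the sorted wild-type libraries. Of 5 root cap genes, 4 fell and 1 was not called (4 lower adjusted over the list alone), with a median log2 fold change of -5.71 (camera adjusted p = 1.43e-06; adjusted p = 0.134 with an estimated correlation, lowest of 9 alternatives 2.68e-07). The root cap transcription factor gene BRN1 (AT1G33280, chromosome 1, 12072611 to 12073965, 3 exons) was at 0.405 ± 0.162 CPM in the mutant and 61.8 ± 6.70 in wild type, and BFN1, a nuclease gene of dying cells, fell by 5.71. Of 12 root hair and epidermis genes, 9 fell and 3 were not called (10 lower adjusted over the list alone; camera adjusted p = 1.30e-06; adjusted p = 0.0687 with an estimated correlation, lowest of 9 alternatives 1.54e-07). Their median was -2.67, with GL2, a regulator of epidermal cell fate, at -2.78 and the cell wall protein gene PRP3 at -2.63. Of 17 wounding and rapid stress genes, 9 rose and 0 fell (11 higher adjusted over the list alone), with a median of 1.27 (camera adjusted p = 7.00e-05; adjusted p = 0.424 with an estimated correlation and 0.0604 by fry, lowest of 9 alternatives 5.45e-07). CML37 rose by 4.33 and HSP70-4 by 3.66, from 89.8 ± 22.5 to 1132 ± 921 CPM.

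Genes of ground tissue identity rose in mutant endodermis, 5 of 9 with 0 lower (6 higher adjusted over the list alone), at a median log2 fold change of 1.23. The camera adjusted p was 4.55e-05, lost at adjusted p = 0.190 with an estimated correlation (lowest of 9 alternatives 1.94e-05). SCL3 rose from 9.39 ± 0.319 to 112 ± 25.3 CPM (log2 3.58) and MGP by 1.98. SCR, a regulator of endodermal fate named here after its values were seen, rose from 274 ± 53.0 to 792 ± 146 CPM (log2 1.53). Both cortex genes tested had higher values, and AED3 was called (log2 4.78), while the list was not (camera adjusted p = 0.102, fry 0.00331).

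Cell cycle genes did not move in 1 direction as lists in mutant endodermis, where the simulation, at a stricter threshold, recovered few 2-fold changes. For change in either direction, fry gave adjusted p = 0.0165 for S phase and 0.0161 for mitosis, and DESeq2 called 5 members of each list. Of 21 S phase genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 0.697). The helicase subunit gene MCM5 rose by 1.26, and the D-type cyclin genes CYCD3;1 and CYCD3;3 fell by 1.76 and 1.31. CYCD3;1 overlaps AT4G34150 on its own strand and is uncertain. Of 23 mitosis genes, 2 rose and 0 fell (1 higher adjusted over the list alone), with a median of -0.06, a mean of -0.03 and the camera direction upward (adjusted p = 0.975). The cytokinesis syntaxin gene KNOLLE rose by 2.09 and CDKB2;2 by 1.00. Root meristem regulators had 4 of 12 higher and 0 lower (5 and 0 adjusted over the list alone) and a median of 0.77 (camera adjusted p = 0.0654, range over 9 alternatives 9.87e-04 to 0.680, the lowest without mutant replicate 1 and 0.0459 without wild-type replicate 2). GIF1 rose by 2.02, and WOX5, a gene of the stem cell niche, rose from 0.357 ± 0.172 to 8.41 ± 3.74 CPM. Of these, the calls of MCM5, CDKB2;2 and CYCD3;3 were lost without wild-type replicate 1 (edgeR adjusted p = 0.0546, 0.152 and 0.0507), replicate 2 (0.0609, 0.160 and 0.125) or replicate 3 (0.0610, 0.144 and 0.0910). CDKB2;2 and CYCD3;3 were also lost without mutant replicate 3 (0.0813 and 0.0553), and CYCD3;1 without wild-type replicate 2 (0.0880) or 3 (0.0633). CDKB2;2 was also lost with upper-quartile factors (0.0570) and with no low-count filter (0.0699), and CYCD3;3 with limma-voom (0.0922). Over the 15 alternatives the adjusted p ranged up to 0.0610 for MCM5, 0.160 for CDKB2;2, 0.125 for CYCD3;3 and 0.0880 for CYCD3;1.

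Among the nutrient and water lists, single genes changed in mutant endodermis without a call for the list in the main camera test. The iron deficiency list had 1 of 8 members higher, the coumarin synthesis gene F6H1 (log2 3.64), and 4 lower, with the coumarin exporter gene ABCG37 at -2.44 (1 and 4 adjusted over the list alone; camera adjusted p = 0.266, fry 0.0302). Of 16 aquaporin genes, 4 fell and 0 rose, with PIP2;4 at -1.81 and PIP1;3 at -1.58 (4 lower adjusted over the list alone; camera adjusted p = 0.216). Of 10 abscisic acid response genes, 4 rose and 0 fell, with COR47 at 2.07 and the phosphatase gene PP2CA at 1.84 (4 higher adjusted over the list alone). The camera adjusted p of that list was 0.0770, but 0.0193 without mutant replicate 2 and 0.0408 with the replicate number as a block (range over 9 alternatives 0.0193 to 0.680). The nitrate and phosphate list had 2 of 5 lower and 0 higher (the same counts adjusted over the list alone; camera adjusted p = 0.201, fry 0.00721). Its called members were the transporter genes NRT1.1 (log2 -1.34) and PHT1;1 (log2 -2.30), and 42.5% of the exon sequence of PHT1;1 also occurs elsewhere, in its neighbouring copies, so its value is uncertain. NRT1.1 was not called without wild-type replicate 2 or 3 (edgeR adjusted p = 0.0928 and 0.0864) or with limma-voom (0.101, highest of the 15 alternatives), nor PHT1;1 without replicate 1, 2 or 3 (0.0858, 0.128 and 0.0865, the middle value the highest of 15) or with limma-voom (0.0844). Of 8 xylem, 2 phloem and 3 stele and pericycle genes tested, 0 were called in either direction by edgeR, DESeq2 or limma-voom, 0 were called adjusted over the list alone and 0 had an unadjusted p under 0.05, and the lists were not called (camera adjusted p = 0.411, 0.697 and 0.863).

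The genes named for their fitted fold change in mutant endodermis included some at or near 0 counts in either genotype. AT5G19880, a peroxidase gene, had 0 counts in wild type and 6.41 ± 3.48 CPM in the mutant, at least 126-fold higher (edgeR adjusted p = 0.00269). The laccase gene LAC12 rose from 0.0628 ± 0.0179 to 17.8 ± 3.61 CPM (log2 7.94), and the kelch repeat gene AT3G07720 from 2.27 ± 0.188 to 195 ± 56.5 (log2 6.42). AT1G40104, AT2G08986 and AT2G07981 also rose, the first and second with ratios of 411 (113 to 3404) and 186 (50.8 to 1551) and the last with a log2 fold change of 7.62. These 3 genes share 18.7%, 37.3% and 43.1% of their exon sequence with other loci, among them each other, so their values are uncertain. The 6 falls named this way all had 0 counts in the mutant: AT4G38690 was at least 155-fold lower, AT5G54585 at least 125-fold, LAS1, which encodes lanosterol synthase, at least 122-fold, AT4G13495 at least 102-fold, AT2G21550 at least 98.8-fold and AT5G39080 at least 75.3-fold. The authors' deposited table lists AT4G38690 at 0.442 FPKM in the mutant and 14.9 in wild type, and LAS1 at 0.0486 and 5.56. Its log2 ratios were -5.08 for AT4G38690, -3.93 for AT5G54585, -6.84 for LAS1, -6.401 for AT2G21550 and -4.87 for AT5G39080. Each of these is a smaller fall than the bound given above for that gene. The bounds therefore hold for the raw count table only and are not minimum folds under other processing of the same reads. AT4G13495 overlaps AT4G13494 on its own strand and is uncertain.

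In mutant whole roots, Casparian strip genes were again lower. DIR16 fell from 294 ± 34.1 to 3.47 ± 2.15 CPM and CASP2 from 74.4 ± 15.7 to 0.953 ± 0.525. The peroxidase gene AT4G36430, among the 5 largest rises by fitted fold change, went from 7.65 ± 3.31 to 271 ± 52.7 CPM. Of 19624 genes tested, 638 were higher and 559 lower in the mutant (edgeR adjusted p under 0.05). These 1197 calls became 1876 without wild-type replicate 1, 596 without wild-type replicate 3, and 652, 651 and 594 without mutant replicate 1, 2 and 3. They became 2657 with limma-voom and 142 in 1 fit of all 12 libraries.

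Of 21 Casparian strip genes, 17 fell, 0 rose and 4 were not called in mutant whole roots (17 lower adjusted over the list alone), with a median log2 fold change of -3.39. This list was called under both correlations (camera adjusted p = 6.01e-139, and adjusted p = 0.0115 with an estimated correlation). CASP1 (AT2G36100, chromosome 2, 15159591 to 15160799, 3 exons) fell from 267 ± 44.5 to 8.66 ± 1.17 CPM (log2 -4.94, SE 0.17, edgeR adjusted p = 1.03e-06). CASP2 and DIR18 had log2 fold changes of -6.28 and -5.46, and DIR24, PER64 and ESB1 of -4.34, -3.47 and -3.25. DIR16, DIR9 and PER9 were among the 5 largest falls by fitted fold change, at -6.41, -5.71 and -5.50, together with CASP2 and AT1G43020 (log2 -5.54), a gene of unknown function. The 5 largest rises on that scale were AT5G19880, with a ratio of 182 (50.1 to 1513), LAC12 (log2 5.83), the chitinase gene AT2G43620 (5.67) and the peroxidase genes AT2G18150 (5.20) and AT4G36430 (5.14).

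**Figure D2:**
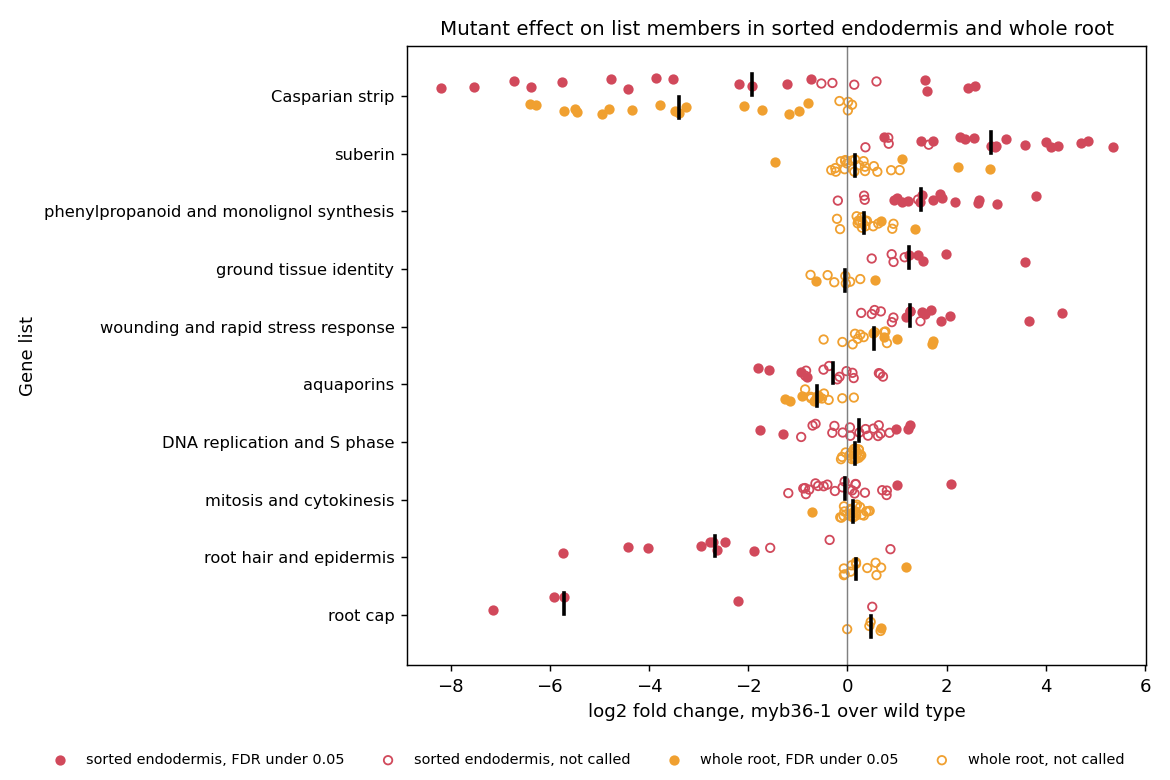
Log2 fold change of mutant over wild type for the members of 10 gene lists, with sorted endodermis in red and whole root in orange. Filled points passed edgeR adjusted p under 0.05 and bars mark medians. The Casparian strip medians are -1.93 in endodermis and -3.39 in whole root, and the suberin medians 2.89 and 0.15.

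Fewer suberin and phenylpropanoid genes were called in mutant whole roots. Of 23 suberin genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone), with a median log2 fold change of 0.15. The acyltransferase gene FACT rose from 24.6 ± 8.73 to 180 ± 20.7 CPM (log2 2.87), and FAR1 and ABCG2 rose by 2.24 and 1.11, while the transcription factor gene MYB92 fell by 1.47; FAR1 and MYB92 were named after their values were seen. The camera adjusted p was 0.00294, lost at adjusted p = 0.608 with an estimated correlation, the highest of 9 alternatives (lowest 2.01e-05), at 0.227 by fry and at 0.107 without wild-type replicate 1. Of 18 phenylpropanoid genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone), with 4CL3 at 1.36 and a list median of 0.33 (camera adjusted p = 1.58e-04; adjusted p = 0.608 with an estimated correlation, 0.179 by fry, lowest of 9 alternatives 9.00e-08). Of 16 wounding genes, 5 rose and 0 fell (7 and 1 adjusted over the list alone), with WRKY53 at 1.70 and a median of 0.53 (camera adjusted p = 3.84e-05; adjusted p = 0.0763 with an estimated correlation, lowest of 9 alternatives 1.18e-05). Of 16 aquaporin genes, 6 fell and 0 rose (12 lower adjusted over the list alone), with TIP2;3 at -1.17 and a median of -0.62 (camera adjusted p = 6.26e-09; adjusted p = 0.487 with an estimated correlation, 0.0985 by fry, lowest of 9 alternatives 1.56e-11). WRKY53 was not called in 1 fit of all 12 libraries (edgeR adjusted p = 0.0587, lowest of 15 alternatives 2.11e-11).

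Root hair and root cap genes were not lower in mutant whole roots. The root hair list had 1 of 12 genes higher, LRX1 (log2 1.18), and the root cap list 1 of 5, BRN2 (log2 0.68), with 0 lower in both (1 and 2 higher adjusted over the list alone). The camera adjusted p was 0.0834 for the root hair list and 0.0728 for the root cap list. The root hair list was called without wild-type replicate 2 (1.34e-04) or mutant replicate 2 (0.0450), and the root cap list without wild-type replicate 1 (0.0413) or 2 (0.0427); over 9 alternatives they ranged from 1.34e-04 to 0.625 and from 0.0413 to 0.608. BRN1 was at 8.84 ± 1.08 CPM in the mutant and 8.87 ± 1.65 in wild type. Of 9 ground tissue genes, 1 rose, MGP (log2 0.55), and 1 fell, MYB74 (log2 -0.63) (1 and 2 adjusted over the list alone; camera adjusted p = 0.405). Of 11 xylem genes, 0 were called by edgeR or DESeq2, 0 adjusted over the list alone and 2 by limma-voom, 3 had an unadjusted p under 0.05, and the median was -0.31. The xylem list had a camera adjusted p of 0.0497, lost at adjusted p = 0.608 with an estimated correlation and at 0.227 by fry. It was also lost without wild-type replicate 2 (0.162) or 3 (0.120) or mutant replicate 1 (0.0964) or 3 (0.109), with a lowest value of 0.00408 over 9 alternatives. Of 7 stele and pericycle genes, 1 fell, the potassium channel gene SKOR (log2 -1.41; 2 lower adjusted over the list alone). Its list had a camera adjusted p of 0.0608 and was called without wild-type replicate 1 (0.0413) or 2 (0.0248) or mutant replicate 2 (0.0427), with a highest value of 0.482 over 9 alternatives.

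The remaining lists were not called in mutant whole roots. Of 20 S phase genes, 11 root meristem regulators, 7 phloem and 2 cortex genes, 0 were called by edgeR, with 1, 4, 1 and 1 at an unadjusted p under 0.05 and as many called by limma-voom. DESeq2 called 1 phloem gene and 0 of the others, and 1 phloem gene was lower adjusted over the list alone. Their camera adjusted p were 0.166, 0.0788, 0.405 and 0.233. Without wild-type replicate 1 the S phase and meristem lists were called (0.0190 and 0.0177, the lowest of 9 alternatives, with highest values of 0.625 and 0.608). Of 23 mitosis genes, 1 fell, CYCB2;3 (log2 -0.72; 1 lower adjusted over the list alone; camera adjusted p = 0.352), which shares 17% of its exon sequence with AT1G20590 and is uncertain. F6H1 rose by 1.15, as 1 of 13 iron deficiency genes (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.352). The abscisic acid list had 2 of 11 lower, with LTI30 at -0.78 (2 lower adjusted over the list alone; camera adjusted p = 0.0788, and 0.0112 without wild-type replicate 1 and 0.0427 without mutant replicate 2, highest of 9 alternatives 0.636). The nitrate transporter gene NRT1.5 fell from 690 ± 89.7 to 338 ± 38.5 CPM, as 1 of 6 members of its list (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.352). Several of these single-gene calls were small. LRX1 was lost without wild-type replicate 3 (edgeR adjusted p = 0.171), mutant replicate 1 (0.135) or 3 (0.172), and LTI30 without wild-type replicate 3 (0.0958) or mutant replicate 1 (0.0570). MGP and BRN2 were lost without wild-type replicate 3 (edgeR adjusted p = 0.118 and 0.119) or mutant replicate 1 (0.0916 and 0.0807), 2 (0.0978 and 0.101) or 3 (0.0642 and 0.0868). In 1 fit of all 12 libraries these 4 and CYCB2;3, NRT1.5, SKOR and F6H1 were not called, at edgeR adjusted p from 0.0509 for F6H1 to 1 for BRN2 and LTI30, the highest of their 15 alternatives.

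The calls in the sorted and whole-root comparisons shared more genes of the same direction than independent lists would. Fisher's exact test takes genes as independent, so its p-values do not measure the spread between libraries. Among 17842 genes tested in both, 164 were higher in both, against 77.5 for independent lists (odds ratio 2.78, Fisher's exact p = 1.82e-22), including LAC12, AT4G36430 and AT2G18150. A further 160 were lower in both, against 62.8 (odds ratio 3.49, Fisher's exact p = 4.07e-31), including CASP1, CASP2, PER9 and DIR16. Genes higher in endodermis and lower in whole roots numbered 35, against 75.9 (odds ratio 0.411, Fisher's exact p = 1.91e-08), and the reverse 83, against 64.1 (odds ratio 1.37, Fisher's exact p = 0.0120). PER3 and MYB74, named here after their values were seen, were higher in sorted endodermis and lower in whole roots. Genes lower in sorted endodermis and higher in whole roots lay close to the independent number with DESeq2, at 124 against 111 (Fisher's exact p = 0.184).

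The difference between the genotype effects was tested directly. Suberin genes had a median interaction of 2.48 on the log2 scale, with 17 of 23 members higher in the sorted comparison and 1 lower, FAR1, named after its values were seen (19 and 1 adjusted over the list alone). This list's call (camera adjusted p = 2.04e-12) was lost at adjusted p = 0.0799 with an estimated correlation (lowest of 15 alternatives 3.62e-16). Root cap genes had a median of -6.22 (0 higher, 4 of 5 lower) and root hair genes of -3.01 (0 higher, 10 of 12 lower), with the same counts adjusted over the list alone. Of 20302 genes tested, 2803 had a higher and 2955 a lower log2 fold change in endodermis than in whole roots (edgeR adjusted p under 0.05). Of these 5758 genes, 4472 were called in endodermis and 473 in whole roots, 118 of them in both with opposite signs and 177 in both with the same sign. The interaction fit shares 1 spread over all 12 libraries, which is smaller than that of endodermis alone, and limma-voom kept 4415 of the 5758 calls. The root cap and root hair lists were called under both correlations (camera adjusted p = 6.92e-09 and 5.04e-08, and adjusted p = 0.0293 and 0.0407 with an estimated correlation).

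The Casparian strip list had a positive interaction, with a median of 1.27 and 11 genes higher and 1 lower of 21 (the same adjusted over the list alone; camera adjusted p = 4.40e-04; adjusted p = 0.369 with an estimated correlation, lowest of 15 alternatives 2.35e-05). CASP1 had an interaction of 1.40, ESB1 of 2.02 and PER64 of 1.27, and the 1 lower was PER9 (-2.72). Phenylpropanoid genes had a median of 1.02, with 8 of 18 higher and 0 lower (11 higher adjusted over the list alone; camera adjusted p = 2.06e-06; adjusted p = 0.352 with an estimated correlation, lowest of 15 alternatives 2.13e-08). Ground tissue genes had a median of 1.41, with 7 of 9 higher and 0 lower (8 higher adjusted over the list alone; camera adjusted p = 6.10e-06; adjusted p = 0.0799 with an estimated correlation, lowest of 15 alternatives 1.80e-06). Wounding genes had a median of 0.89, with 4 of 17 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0420; adjusted p = 0.665 with an estimated correlation, lowest of 15 alternatives 0.00674). The wounding call was lost without mutant sorted replicate 1 (0.287), wild-type sorted replicate 2 (0.0573) or wild-type whole-root replicate 2 (0.0501), and by fry (0.156). The 1 lower was WRKY53.

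The lists without a called interaction still held single genes. Camera gave adjusted p of 0.905 for S phase (1 higher and 3 lower of 21), mitosis (1 and 1 of 23), xylem (0 and 1 of 11), phloem (0 and 0 of 7 by edgeR, 1 called by DESeq2, 0 by limma-voom and 1 at an unadjusted p under 0.05) and stele (0 and 1 of 7), 0.197 for meristem regulators (3 and 0 of 12) and 0.187 for cortex (1 and 0 of 2). For the remaining lists it gave 0.293 for iron deficiency (2 and 4 of 13), 0.300 for aquaporins (2 and 2 of 16), 0.0894 for abscisic acid (4 and 1 of 11) and 0.187 for nitrate and phosphate (0 and 2 of 6). Adjusted over the list alone, the counts were the same except for mitosis (1 and 0), xylem (0 and 0), aquaporins (2 and 1) and abscisic acid (5 and 1). By fry, cortex, iron deficiency, and nitrate and phosphate were called (adjusted p = 0.00494, 0.00908 and 0.00494). The abscisic acid list was called without mutant sorted replicate 2 (0.00736) or wild-type whole-root replicate 1 (0.0372), with a highest value of 0.672 over 15 alternatives, and the meristem list without mutant sorted replicate 1 (0.0121, highest of 15 alternatives 0.881). Named for their fitted interaction were GLIP2, ALD1 and AT1G40104 among the rises, and AT2G21550, LAS1 and AT4G13495 among the falls; where a sorted group had 0 counts, as for all but AT1G40104, this value depends on the prior count and is no bound. GLIP2, a lipase gene, had 51 counts in mutant and 0 in wild-type sorted cells, and in whole roots it fell from 7.90 ± 2.04 to 0.229 ± 0.0709 CPM (log2 -5.07). ALD1, of pipecolic acid synthesis, had 30 counts in mutant and 0 in wild-type sorted cells, and a whole-root log2 fold change of -1.09 (edgeR adjusted p = 0.0680). LAS1, AT4G13495 and AT2G21550 had 0 counts in sorted mutant cells and whole-root log2 fold changes of -0.64, -0.58 and 0.13, none called by edgeR (adjusted p = 0.0989, 0.260 and 0.706).

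**Figure D3:**
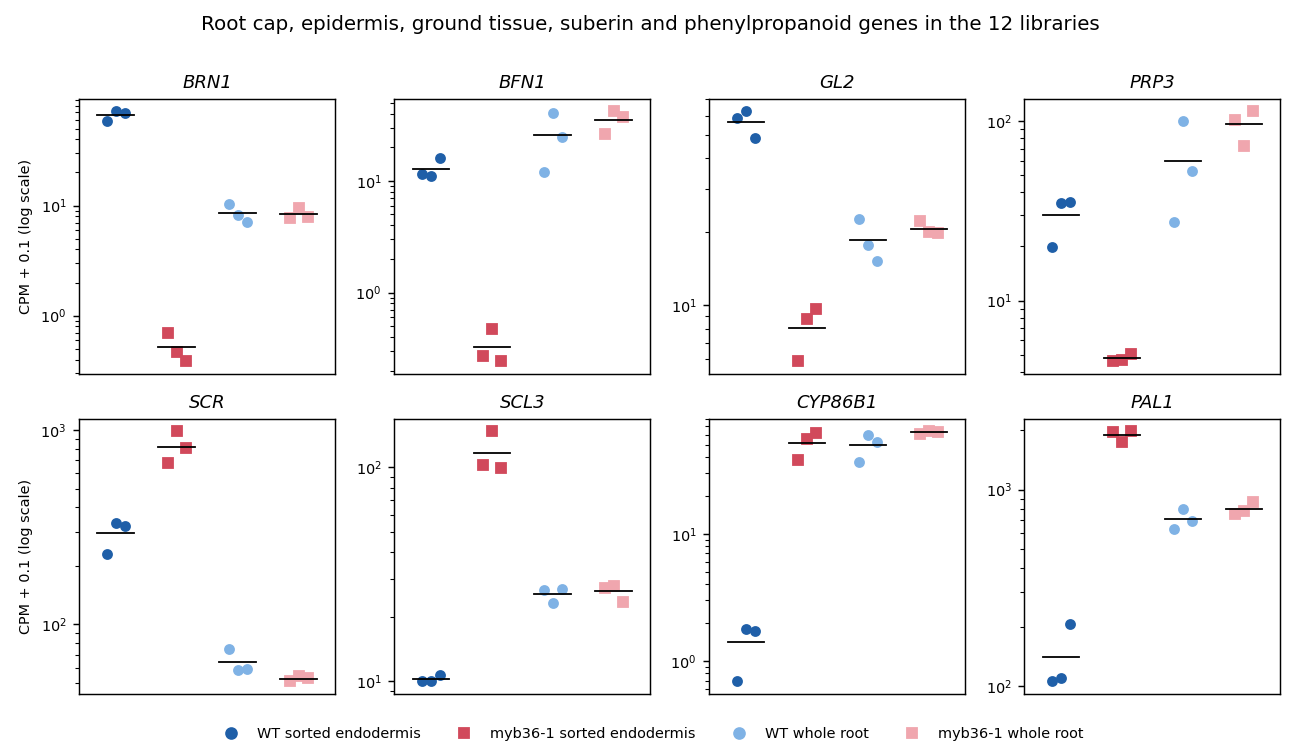
Levels of the root cap genes BRN1 and BFN1, the epidermal genes GL2 and PRP3, the ground tissue genes SCR and SCL3, CYP86B1 and PAL1 in each of the 12 libraries, as TMM-scaled CPM plus 0.1 on a log axis, with 1 point per library and a line at each group's mean. BRN1 and GL2 are lower in the sorted mutant libraries than in all other libraries, and the whole-root levels of both genotypes lie close together.

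Wild-type sorted endodermis was set against wild-type whole root to show what the sort held. Casparian strip genes were higher in sorted cells, with PER64 at 588 ± 104 against 104 ± 15.6 CPM, and vascular genes lower, with the xylem protease gene XCP2 at 1.24 ± 0.243 against 146 ± 26.6. Root cap genes were also higher in sorted cells, with BRN1 at 67.6 ± 7.35 against 8.25 ± 1.51 CPM, and wounding genes were higher, with WRKY40 at 420 ± 39.5 against 3.47 ± 0.818. Suberin genes were lower, with ABCG2 at 0.964 ± 0.136 against 51.5 ± 9.83 CPM. Of 19747 genes tested, 6587 were higher and 6983 lower in sorted cells (edgeR adjusted p under 0.05). All 13 lists called by camera here were lost with an estimated correlation, at adjusted p from 0.112 to 0.692.

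By list, 17 of 21 Casparian strip genes were higher in sorted wild-type cells and 1 lower (median log2 1.82, camera adjusted p = 5.81e-07; adjusted p = 0.357 with an estimated correlation), with PER64 at 2.49 and UCC1 at 2.57. Ground tissue genes were higher in 6 of 9 and lower in 2 (0.0267), with MYB74 at 3.91 and SCR at 2.26. Root cap genes were higher in 4 of 5, with BRN1 at 3.03, and lower in 1, BFN1 (median 1.70, camera adjusted p = 0.0299). Root hair genes went both ways, 3 higher, WER at 2.31 among them, and 4 lower of 12, with a median of -0.36, a mean of 0.01 and no call (camera adjusted p = 0.714). All 11 xylem genes, all 7 phloem genes and 4 of 6 stele genes were lower (medians -5.15, -4.00 and -4.26; camera adjusted p = 3.86e-14, 5.95e-07 and 2.25e-04). PHO1 of the stele was at -6.84, and the phloem gene SEOR1 had 2 counts in sorted cells, a ratio of whole root over sorted of 526 (145 to 4345). Both cortex genes were lower, AT1G62510 at -3.16 (camera adjusted p = 0.142). Suberin genes were lower in 15 of 23 and higher in 2 (median -2.67, camera adjusted p = 1.02e-06), and phenylpropanoid genes were split 6 to 6 of 18, with 4CL3 at 2.20 (camera adjusted p = 0.769). Wounding genes were higher in 15 of 17 and lower in 1 (median 3.70, camera adjusted p = 1.51e-15). Adjusted over the list alone, the counts of these lists were the same except for root hair, at 3 and 3.

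Proliferation lists were slightly higher in sorted wild-type cells, S phase in 15 of 21 with 2 lower, mitosis in 16 of 23 with 2 lower and meristem regulators in 6 of 11 with 1 lower (medians 0.62, 0.71 and 0.71, camera adjusted p = 0.0428 for each). MCM7 was at 1.15, CYCA2;3 at 1.72 and PLT2 at 2.06. These 3 list calls were lost without sorted replicate 2 (0.0964, 0.0754 and 0.0754) or whole-root replicate 2 (0.0593, 0.0742 and 0.0593), and S phase also without whole-root replicate 3 (0.0620); the highest of 9 alternatives were 0.692, 0.692 and 0.411. Iron deficiency genes were lower in 8 of 13 and higher in 1, with IRT1 at -8.84 (camera adjusted p = 0.0293, and 0.0587 without sorted replicate 2, highest of 9 alternatives 0.330). Nitrate and phosphate genes were lower in 4 of 5 and higher in 1, with NRT1.5 at -8.79 (camera adjusted p = 4.75e-06). Aquaporin genes were higher in 9 of 16 and lower in 4, with PIP2;3 at 2.49, which shares 16.5% of its exon sequence with PIP2;2 and is uncertain (camera adjusted p = 0.516). Abscisic acid genes were higher in 2 of 11, NCED3 at 2.83 among them, and lower in 5 (camera adjusted p = 0.755). The counts adjusted over the list alone were the same for these 7 lists. Named for their fitted fold change were, among rises, DDF1, at least 264-fold, AT1G73510, at least 177-fold, and HSP17.6II, with a ratio of 2018 (558 to 16670.3), and, among falls, UMAMIT31, at least 473-fold lower, AT1G05310, at least 259-fold, and PEN3, at least 212-fold. MYB36 itself was higher in sorted cells (log2 2.59, SE 0.23, edgeR adjusted p = 7.79e-06).

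The authors' deposited table for sorted cells marks 3608 entries as significant, 2794 higher and 814 lower in the mutant, 242 of them with an infinite ratio. For whole roots the authors' deposited table marks 891, 442 higher and 449 lower. Entries were matched to loci by gene name or synonym, and only genes with a matched entry of status OK were compared. The significant entries gave 3036 loci for sorted cells and 813 for whole roots. Some matches were wrong, as the entry at the position of CYCD3;3 was matched to CYCD3;1, so the counts of agreement are approximate. Of the 12839 genes compared in this way in endodermis, edgeR called 3663. Of these, 2154 were also called in the authors' deposited table, 2150 of them in the same direction. In whole roots, edgeR called 1002 of 14840 such genes, and the authors' deposited table shares 595 of these calls, all 595 in the same direction. The authors' deposited table gives CASP1 as 1377 FPKM in wild-type and 142 in mutant sorted cells (q = 7.26e-08), and MYB36 as 154 and 127 (q = 0.693). These calls rest on the same reads and are not an independent test.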

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

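The tests of loss from whole plants, of the endodermal share and of protoplasting stress were chosen after the result was seen, and the thinning to 1 depth was added after seeing the data. The values here are log2 interactions, the mutant effect in sorted endodermis minus that in whole root, and each passed the edgeR or camera test of the difference. In all, 5758 genes did. The edgeR fit shares 1 spread over all 12 libraries, below that of endodermis alone (common biological coefficient of variation 0.278 against 0.395). With limma-voom 5043 genes were called, 4415 of them among the 5758. Of the 7 lists, root cap and root hair were also called with an estimated correlation (camera adjusted p = 0.0293 and 0.0407), and 5 were not: Casparian strip (adjusted p = 0.369), suberin (0.0799), phenylpropanoid (0.352), ground tissue (0.0799) and wounding (0.665), each the highest of the 15 alternatives for that list, whose lowest values were 2.35e-05, 3.62e-16, 2.13e-08, 1.80e-06 and 0.00674. Wounding was also not called by fry (0.156) or without mutant sorted replicate 1 (0.287), wild-type sorted replicate 2 (0.0573) or wild-type whole-root replicate 2 (0.0501).

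Root cap genes had a median interaction of -6.22 and root hair and epidermis genes of -3.01, with BRN1 at -7.18, BFN1 at -6.22, PRP3 at -3.33, GL2 at -2.98, BRN2 at -2.93 and LRX1 at -2.75; of the 17 members of both lists edgeR called 13 lower in the sorted mutant and 0 in mutant whole roots (0 by DESeq2, 0 by limma-voom, 0 at an unadjusted p under 0.05). A loss of these transcripts from the plants as a whole is argued against by the whole-root median of 0.399 (bootstrap interval over members 0.0624 to 0.585). This interval takes genes as independent and does not measure the spread between libraries, so it is no call of a rise in whole roots. In the sorted comparison the median of the 17 members was -2.65 after thinning, against -2.71 before. Thinning keeps the expected ratio of each gene, so this median could hardly move. It does not decide on lower depth or library quality as the cause. A candidate explanation is that root cap and epidermal cells, which a sort for the endodermis should remove although the labels name no marker for it, entered the wild-type sort more than the mutant sort: in a second root hair list 10 of 16 members were lower in the sorted mutant by edgeR (11 by DESeq2 but 7, fewer than 8 of 16, by limma-voom) and 0 in whole roots (0 by DESeq2, 1 by limma-voom, 0 at an unadjusted p under 0.05), with RHS18 in the sorted mutant at 11.6 ± 4.69 against 69.3 ± 14.8 CPM and ADF8 at 3.47 ± 0.263 against 51.4 ± 10.2. In wild type 4 of 5 root cap genes were higher in sorted cells than in whole root (median 1.70, BRN1 at 67.6 ± 7.35 against 8.25 ± 1.51 CPM). The second root hair list was there lower in 8 of 16 and higher in 1 (median -1.04), and the first had a median of -0.36. In mutant whole roots 2 members of the second list were called higher. Values of the second list in the sorted mutant do not all follow the explanation: CSLD3, its most abundant gene, was at 438 ± 229 against 557 ± 63.4 CPM and not called, and RHS12 was at a log2 fold change of 0.06 where RHS13 was at -5.41. An effect of myb36-1 on these transcripts within the sorted cells was not tested and stays open.

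Suberin genes had a median interaction of 2.48 and phenylpropanoid genes of 1.02, with CYP86B1 at 4.97, PAL1 at 3.59, CAD4 at 3.14 and KCS2 at 2.86. The suberin median was 2.83 after thinning, against 2.89 before. As thinning keeps expected ratios, this does not decide on lower depth or library quality as the cause. The mean rise of suberin genes exceeded that of the ground tissue list by 1.28 (two-sided permutation over genes, p = 0.0227). For phenylpropanoid genes the difference was 0.140 (permutation p = 0.732). The permutation takes genes as independent. In wild type, sorted cells had higher ground tissue genes (median 0.93) but lower suberin genes (median -2.67) than whole root. The ground tissue list is therefore no measure of the share of cells with suberin transcripts. A higher endodermal share of the mutant sort as the whole cause is not decided for either list. A stronger response to protoplasting cannot be told apart from the genotype, since the wounding list also rose (median 1.27) and all sorted libraries went through the sort, although in wild type the sorted cells had higher wounding genes (median 3.70) with lower suberin genes (median -2.67). An effect of myb36-1 on these genes stays open as the biological explanation.

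The Casparian strip list had a median interaction of 1.27, with ESB1 at 2.02, CASP1 at 1.40 and PER64 at 1.27, and PER9 the other way at -2.72. This was not a smaller fall of every member in sorted cells, as 11 of 21 were called higher and 1 lower. CASP2, DIR16, DIR9 and DIR18 fell at least as far in sorted cells as in whole roots. GSO1, RBOHF, PER3 and PER39 rose in sorted cells, which also raises the median. A higher endodermal share of the mutant sort may raise all endodermal genes by a like amount. The Casparian strip median minus that of the ground tissue list was -0.135, with a bootstrap interval over members of -1.77 to 0.242, too wide to separate this from a genotype effect that differs between the tissues. The ground tissue list itself stood at 1.41, with SCL3 at 3.50 and MGP at 1.41.

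The other differences are given as values. Wounding genes had a median of 0.89, with CML37 at 4.37, HSP70-4 at 1.91 and WRKY53 at -1.45. Meristem and cell cycle genes included WOX5 at 4.53, KNOLLE at 2.19, GIF1 at 1.47, MCM5 at 1.096, CYCD3;3 at -1.41 and CYCD3;1, uncertain for its overlap with AT4G34150, at -2.03. Among transport, iron and abscisic acid genes, F6H1 was at 2.47, COR47 at 2.30, PP2CA at 1.96 and TIP2;3 at 1.86, and PIP1;3 at -0.87, NRT1.1 at -1.16, PIP2;4 at -1.36, ABCG37 at -2.06 and PHT1;1 at -2.62. The cortex gene AED3 was at 4.03. Among the genes named for their fitted change, AT3G07720 was at 6.07, LAC12 at 2.12 and AT4G36430 at 1.09, and AT1G40104, AT2G07981 and AT2G08986, which share sequence with each other, were at 7.86, 7.19 and 6.76. For genes with 0 counts in the sorted mutant group the fitted interaction depends on the prior count and is no bound: AT4G38690 was at -8.51, AT5G39080 at -8.66, AT5G54585 at -9.00, AT4G13495 at -10.15, LAS1 at -10.40 and AT2G21550 at -10.84.

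Other splits of the samples were counted for each comparison. For the interaction, 3 of 100 splits drawn, the real one included, gave as many calls as the real 5758, and the highest other split gave 6202. That share is under 0.05, but it reflects a structure of the samples: the 87 splits that mixed the sorted groups gave 0 calls, and the 13 that kept them whole gave 5036 to 6202. Of the 12 of these with other whole-root groupings, 2 gave more calls than the real split, so a random grouping of the whole-root libraries is not excluded for the count of interaction calls. In endodermis, whole roots and sorting, 3 libraries against 3 allow 10 splits, too few for a share under 0.05: the real splits (1 of the 10 in each) gave 5225, 1197 and 13570 calls and the highest other split 0.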

How the results depend on the processing

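Thinning was chosen after seeing the data. Under the alternatives run, 0 called genes changed sign and stayed called, and other scalings moved the median of all genes by at most 0.061 on the log2 scale. The 5225 endodermis calls became 9251 (4493 higher, 4758 lower) in 1 fit of all 12 libraries, which borrows the smaller spread of whole roots, and 2236 to 7017 on leaving out a library: 2512, 2236 and 2764 without wild-type replicate 1, 2 and 3, of which 2503, 2232 and 2760 were among the 5225. The 1197 whole-root calls became 142 (79 and 63) in 1 fit of all 12, 2657 (1379 and 1278) with limma-voom, and 594 to 1876 on leaving out a library: 1876 and 596 without wild-type replicate 1 and 3, and 652, 651 and 594 without mutant replicate 1, 2 and 3. Leave-one-out ranges were 4299 to 7880 for the interaction and 11958 to 13416 for sorting. The shared calls rose from 324 to 504 with DESeq2. Lists called by camera went from 7 to 0 in endodermis, 6 to 1 in whole roots, 7 to 2 for the interaction and 13 to 0 for sorting with an estimated correlation, and in whole roots to 2 with fry and to 10 without wild-type replicate 1 (5 to 10 on leaving out a library). The MYB36 interaction of 0.27, not called, was -0.11 to 0.56 on leaving out a library and reversed without mutant sorted replicate 2 (edgeR adjusted p = 0.805, range over 20 alternatives 0.309 to 0.945). Fewer libraries alone do not account for the changes in calls, as endodermis calls rose to 7017, 5900 and 5444 without mutant replicate 1, 2 and 3. Except where a borrowed spread or the correlation accounts for a change by construction, the cause was not tested.

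Replicate numbers are shared between groups. Same-numbered libraries' deviations correlated at 0.024, 0.223 and 0.00133 in endodermis, 0.258, 0.129 and -0.0391 in whole roots, 0.123, 0.0420 and 0.102 between the wild-type sorted and whole-root libraries, and -0.0722, -0.0577 and -0.0399 between the mutant ones. Every sample correlated best with its own number between the wild-type groups and not in the other 3 comparisons, a hint from the data and not from the design. With the replicate number as a block the calls were 4684 in endodermis (4312 of the 5225 kept), 1512 in whole roots, 5072 for the interaction and 13564 for sorting. Genes lower in endodermis and higher in whole roots numbered 107 with it, against 76.9 for independent lists (Fisher's exact p = 3.86e-04), where DESeq2 gave 124 against 111 (p = 0.184). The block ended the endodermis calls of CDKB2;2 (edgeR adjusted p = 0.0843, highest of 15 alternatives 0.160) and PHT1;1 (0.0536, highest 0.128). With the block the abscisic acid list was called in endodermis (camera adjusted p = 0.0408). Of the named genes, 6 lost their endodermis call and 4 their whole-root call without at least 1 library, and 4 and 10 under at least 1 other alternative. Depth limits the sorted mutant group, where 3 counts in the smallest library are 0.412 CPM, but thinning to 7280556 counts gave 5002 calls, 4821 of them among the 5225.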

Other observations

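The ER body and defence-type lignin lists, and the genes named here, were chosen after the result was seen. Genes of ER bodies, which store beta-glucosidases against herbivores, were lower in mutant sorted endodermis: 7 of 7 fell, with a median log2 fold change of -3.25 and a range of -3.76 to -1.92 (edgeR adjusted p under 0.05 for each). PYK10, the main ER body beta-glucosidase gene, fell from 9465 ± 205 to 698 ± 142 CPM, and the regulator gene NAI1 from 56.4 ± 4.28 to 5.67 ± 0.785. In whole roots 0 of the 7 were called by edgeR, 1 by DESeq2 and 3 by limma-voom, 3 had an unadjusted p under 0.05, and the median was -0.28, with PYK10 at 13944 ± 760 against 16461 ± 1531 CPM. In the same sorted libraries root cap and epidermis markers were also lower, 13 of 17 by edgeR, with 0 lower in whole roots (0 by DESeq2, 0 by limma-voom, 0 at an unadjusted p under 0.05). In wild type, PYK10 in sorted cells was at -0.56 relative to whole root and BGLU22 at 1.16.

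Of the 4 genes put in the defence-type lignin list after the result was seen (MYB15, LAC12, WRKY71 and CYP81F2), edgeR called 3 higher in mutant endodermis and 4 in mutant whole roots. LAC12 was already among the largest rises in both comparisons, so these counts are no test of a defence response. MYB15, a transcription factor gene of defence-induced lignin, rose by 3.27 in sorted endodermis and by 4.91 in whole roots on the log2 scale, where it went from 0.526 ± 0.277 to 16.1 ± 3.47 CPM (edgeR adjusted p = 0.00173 and 3.05e-05). WRKY71 rose by 4.11 and 3.59 and LAC12 by 7.94 and 5.83. In wild type MYB15 was also higher in sorted cells than in whole root, at 30.3 ± 4.93 against 0.489 ± 0.258 CPM (log2 5.92), as was WRKY71 (log2 1.93), and wounding genes had a median of 1.27 in the sorted mutant and 0.53 in mutant whole roots (camera adjusted p = 7.00e-05 and 3.84e-05; adjusted p = 0.424 and 0.0763 with an estimated correlation, the highest of 9 alternatives, lowest 5.45e-07 and 1.18e-05). CYP81F2, of indole glucosinolate modification, rose by 3.71 in whole roots, and its endodermis value of 1.31 was not called (edgeR adjusted p = 0.196).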
